A study of Homo sapiens with 2 samples.

How the data were processed

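CUT&Tag was carried out on CAL27 cells with an antibody against lactylated lysine, with 1 library from untreated cells and 1 from cells given 10 mM lactate for 24 hours. Per the labels' protocols, thawed cells were bound to concanavalin A beads, permeabilised with digitonin and tagmented by antibody-guided pA-Tn5. Per the submitters' processing notes, fastp 0.20.0, BWA and MACS2 2.1.0 were used with the build hg38. Per the file headers, peaks were called in each library separately, without a control, by MACS version 2.1.0.20150420 at a q threshold of 0.05, with a shift of -100 bp, an extension of 200 bp and an effective genome size of 3099750718. The shift with extension centres each tag's window on the cut, as fits a transposase assay. The input names in the headers carry the tags uni and dedup. Whether spike-in scaling was applied is not given in the sources used here. No library without antibody was used here, so tagmentation of open chromatin is not separated from the antibody's signal.

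The authors' deposited lists give for each peak summit a pileup, which is a signal in tags not scaled for depth, and a fold enrichment, which is a ratio to the local background with 1 added to both. The lists used carry neither a p nor a q column. The background was therefore recomputed from pileup and fold, and −log10 p from the Poisson upper tail. The lowest recomputed background, 1.01 in the library labelled untreated and 0.976 in the library labelled lactate, equals the genome-wide background from each library's tags.

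The file headers conflict with the sample labels. In both lists the run name, the input file and every peak name carry the other sample's name, and the name line carries the label's. The samples were kept as labelled.

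The 49750 and 58929 summits were collapsed to 43680 and 50352 regions of the same start and end, each represented by its summit of highest fold. A region was shared when it overlapped a region of the other library by at least 1 bp, and random overlap was the mean of 100 placements on the same chromosomes. Genes came from the RefSeq table for GRCh38.p14, the same build as the peaks. The table used has no strand, transcripts or exons. The planned promoter window around each transcription start was therefore replaced by 1 kb to both sides of either end of the gene, and no exon or intron split was made. A gene was marked when a region overlapped those windows. Of 508 list symbols, 507 were counted, since T and TBXT are 1 gene. Each list's count was set against 10000 random lists of as many protein-coding genes, as a description of these libraries. Matching on promoter GC was planned but needs a genome sequence, which was not used here, and motif content was not analysed for the same reason.

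The named genes were set by a rule written before the data were examined. They were the 12 genes of highest value in each library alone, the 8 highest of each library among genes marked in both, up to 4 members of each list marked in 1 library alone and up to 2 marked in both, 10 genes always given (LDHA, SLC16A1, SLC16A3, EP300, HIF1A, VEGFA, MYC, TP63, CDH1 and ACTB), and the 5 highest regions of each library alone over 10 kb from any gene end. The rule ranked by q, else p, else fold enrichment, and fold enrichment was used. List members marked in both were ranked by the library labelled lactate. Some genes that the rule names are not reported here. The 19 lists covered glycolysis and lactate transport, hypoxia, lysine acyl writers, erasers and readers, epithelial-mesenchymal transition, angiogenesis, cell cycle, squamous epithelium, growth factor, AP-1 and YAP signalling, interferon and inflammation, ribosomal proteins, mitochondrial respiration, histones, DNA repair, developmental transcription factors and 5 sets of markers of other cell types.

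Depth was 15696147 and 15120031 tags. With 1 library per group no test was run, and the 95% intervals, exact Clopper-Pearson, cover counting error only. Tags are not independent molecules. Alternatives tried were stricter thresholds, equal lists, other overlap rules, other windows, sex chromosome Y and unplaced sequences left out, and a rule for gene-end peaks added after the data were seen. The overlap count was checked against bedtools 2.31.1, which gave the same 31120 and 30822 regions. As a check of the code, peaks were planted inside the gene-end windows of 200 genes. All 200 of 200 genes were recovered, which the placement fixed in advance. In simulated data, marks were drawn independently at the share of the library labelled untreated over 20037 genes. There, 5 of 200 unrelated lists of 30 genes lay above the 97.5th percentile and 5 below the 2.5th. Of lists with 80% marked, 50 of 50 lay above the 97.5th. The difference between the libraries was not simulated. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.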

Results

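Lysine lactylation was mapped by CUT&Tag in CAL27, an established human oral squamous cell carcinoma line. In this assay an antibody, here against lactylated lysine on any protein, directs a protein A-Tn5 transposase to cut and tag the DNA beside the modification. There were 2 libraries, 1 from untreated cells and 1 from cells exposed to 10 mM lactate for 24 hours. The library labelled untreated held 15696147 tags and the library labelled lactate 15120031. Each group had 1 library, so no difference between them has a replicate check, no p-value is given, and the 95% intervals (exact Clopper-Pearson) cover counting error only. The header of each peak list conflicts with its sample label: in both lists the run name, the input file and the names of all peaks, 49750 in the list deposited for the untreated sample and 58929 in the other, carry the name of the other sample. Only the name line of each header carries the label's name. The sample labels were kept, and the groups are called the library labelled untreated and the library labelled lactate. Every direction given between them would turn if the lists were exchanged.

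The first comparison asked how many sites carried the mark and which were the same in both libraries. Peaks at PHF14, PARK7 and ZNF484 were among the strongest gene-end peaks that both libraries shared. At the lower end of PHF14, which encodes a PHD finger protein, the peak spanned chromosome 7 from 10973589 to 10973982 in the library labelled untreated and from 10973589 to 10973968 in the library labelled lactate, with fold enrichments of 14.1 and 13.4 over the local background. PARK7, which encodes the protein deglycase DJ-1, carried the highest gene-end enrichment of the genes marked in both in the library labelled untreated (14.3, chromosome 1 from 7961379 to 7961826), and ZNF484 the highest in the library labelled lactate (14.4, chromosome 9 from 92877889 to 92878378). Fold enrichments are the authors' own values for each peak. They serve to rank peaks within 1 list. Between the lists they enter the stricter threshold on fold enrichment, applied to both lists. They also enter medians over shared sites and over genes marked in both, given in a later part. With the pileup, they also gave the recomputed p. Coordinates are on hg38.

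The library labelled lactate had 50352 peak regions and the library labelled untreated 43680, a ratio of 1.15, with 0.963 times as many tags. Its regions covered 19.4 Mb against 15.9 Mb, and their median length was 320 bp against 304 bp. Of the regions in the library labelled untreated, 31120 overlapped a region of the other by at least 1 bp (71.3%, interval 70.8 to 71.7). Of those in the library labelled lactate, 30822 did (61.2%, interval 60.8 to 61.6). Regions placed at random on the same chromosomes overlapped in 1.41% and 1.23% of cases. The median local background of mitochondrial peaks was 162.1 per 1000000 tags in the library labelled untreated and 293.6 in the library labelled lactate. Sharing left 12560 regions in the library labelled untreated alone and 19530 in the library labelled lactate alone.

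Sharing followed peak strength. Among the weakest 10% of peaks 35.9% of the regions of the library labelled untreated and 26.2% of those of the library labelled lactate were shared, and among the strongest 10% 99.5% and 99.1%. Among these strongest peaks 21 regions were in the library labelled untreated alone and 45 in the library labelled lactate alone.

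**Figure D1:**
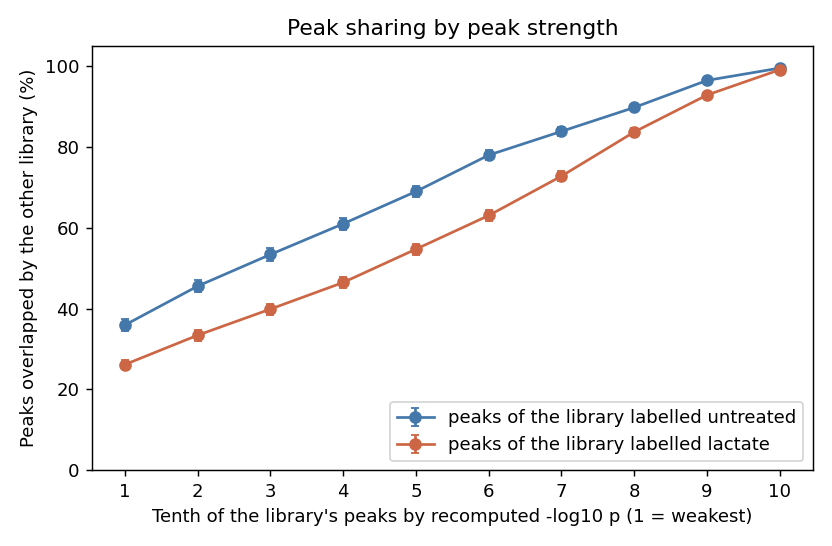
Percent of each library's peak regions overlapped by a region of the other library (vertical axis) in 10 equal bins of recomputed −log10 p within that library (horizontal axis, bin 1 is the weakest); points are shares and bars exact 95% binomial intervals. The share climbed from 35.9% to 99.5% in the library labelled untreated and from 26.2% to 99.1% in the library labelled lactate.

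The next comparison was of where in the genome the mark lay. Ends of protein-coding genes, taken as 1 kb to both sides of either end of the annotated gene, make up 2.36% of the genome and held 19.3% of the peak summits in the library labelled untreated (interval 19.0 to 19.7) and 19.8% in the library labelled lactate (interval 19.5 to 20.2), 8.19 and 8.41 times the genome's share. The order of the libraries turned under both stricter thresholds, with 22.9% and 21.7% at a fold enrichment of at least 5 and 23.8% and 23.1% at a recomputed −log10 p of at least 7. The annotation used carries no strand, so promoters and 3′ ends were counted together. Inside protein-coding genes, away from their ends, lay 38.5% and 39.1% of summits, and outside annotated genes 30.2% and 29.5%. Of the shared regions, 7202 of 30958 in the library labelled untreated (23.3%, interval 22.8 to 23.7) and 7052 of 30656 in the library labelled lactate had their summit at a gene end. Of the regions in 1 library alone, 14.9% did in the library labelled lactate (interval 14.4 to 15.4) and 9.55% in the library labelled untreated (interval 9.04 to 10.1).

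Over 10 kb from any gene end lay 8149 of the regions in the library labelled lactate alone (41.8%) and 6072 of those in the library labelled untreated alone (48.6%). The strongest of the former was on chromosome 3 from 105274944 to 105275226, 91.8 kb from ALCAM, a cell adhesion molecule gene, with a fold enrichment of 10.3. The next ones lay 470.4 kb from AKR1E2, 92.7 kb from LRRC7, inside COA1 and inside ZBTB20. In the library labelled untreated the strongest lay on chromosome 16 from 34071480 to 34071737, 279.9 kb from CCNYL1B, with a fold enrichment of 11.9, followed by regions 229.7 kb from LRIG3, 669.5 kb from H3-7, 19.2 kb from FOXN2 and inside BAZ2B. Repeat and artefact-prone stretches were not filtered out here, so the reads of such distal regions are uncertain.

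The gene-level comparison asked which protein-coding genes carried the mark at an end in 1 library and not in the other. TMPRSS11F, a transmembrane serine protease gene, RTN2, CMC1, AIFM1 and CTSS, the cathepsin S gene, carried strong peaks in the library labelled lactate alone. SRP72, NFRKB, IFNW1 and ENTPD3 did so in the library labelled untreated alone. Of 20037 protein-coding genes, 7975 were marked in both libraries (39.8%, interval 39.1 to 40.5), 1943 in the library labelled lactate alone (9.70%, interval 9.29 to 10.1), 749 in the library labelled untreated alone (3.74%, interval 3.48 to 4.01) and 9370 in neither. Genes marked in the library labelled lactate alone were 2.59 times as many as those in the library labelled untreated alone. With lists of 21840 strongest regions from each library the ratio was 1.26 (1454 against 1150 genes). Where a peak had to be in the strongest 25%, with no peak of the other library within 5 kb of the gene end, 64 genes were left in the library labelled lactate and 11 in the library labelled untreated. AIFM1 and NFRKB were not among them, since the other library had a peak within 5 kb of an end of each gene.

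TMPRSS11F carried a peak at its upper end, chromosome 4 from 68129750 to 68130119, with a fold enrichment of 11.5 and a pileup of 22 tags. RTN2 carried one on chromosome 19 from 45485292 to 45485608 with a fold enrichment of 9.41. The values were 9.11 at CMC1, 8.56 at AIFM1, which encodes a mitochondrial apoptosis factor, and 8.41 at CTSS. The facing ends of EFHB and RAB5A, a small GTPase gene of early endosomes, shared 1 peak with a fold enrichment of 8.27, on chromosome 3 from 19946826 to 19947434. The other members of the 12 highest, ADGRV1, GOLGA6B, ATAD1, SCAF11 and WDR88, carried peaks that overlapped a peak of the library labelled untreated just outside the gene-end window, so they do not differ in peak presence at the site. In the library labelled untreated alone, the SRP72 peak lay on chromosome 4 from 56467435 to 56467758 with a fold enrichment of 8.07. The enrichments were 7.45 at both NFRKB and IFNW1, 6.80 at ENTPD3, 6.72 at DSTYK and 6.58 at RBBP9. GOLGA6L4, GOLGA6D, KAT6B, PLAUR and PLIN1 also stood among the 12 highest, with peaks that overlapped a peak of the library labelled lactate outside the window. The GOLGA6 genes have near-identical copies, so their reads are uncertain.

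Genes of lactate handling were marked in both libraries. LDHA, the lactate dehydrogenase A gene, carried peaks with fold enrichments of 3.67 (chromosome 11 from 18394383 to 18394882) in the library labelled untreated and 3.55 (from 18394425 to 18394738) in the library labelled lactate. The lactate transporter gene SLC16A1 was also marked in both. Inside SLC16A1 lay 2 peaks in the library labelled untreated, the highest with a fold enrichment of 6.08, and 0 in the library labelled lactate. Inside LDHA lay 1 peak in each library, with 6.4 and 5.43, and inside SLC16A3 also 1 in each. SLC16A3, another lactate transporter gene, was marked in both. Its gene-end peak of highest fold lay from 82216392 to 82217347 on chromosome 17 in the library labelled untreated and from 82217681 to 82218003 in the library labelled lactate. Whether either library also had a weaker peak at the other's place was not examined. EP300, HIF1A and MYC were marked in both. VEGFA and ACTB were marked in the library labelled lactate alone, with fold enrichments of 3.80 and 2.75. Neither library had a peak at an end of TP63, the squamous lineage transcription factor gene, or of CDH1, the E-cadherin gene, but TP63 held 9 peaks inside it in the library labelled untreated and 10 in the library labelled lactate, and CDH1 held 8 and 7.

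Of the 19 gene lists fixed before the data were examined, those of basic cell functions had high shares of marked genes and those of other cell types low ones, in both libraries. Among 40 ribosomal protein genes 33 were marked in the library labelled untreated and 32 in the library labelled lactate, among 25 DNA repair genes 22 and 23, and among 26 replication-dependent histone genes 21 and 24. These 3 lists had more marked members than nearly all of 10000 random lists of the same size in both libraries. Neighbouring histone genes, such as H2BC11 and H2AC11, can be marked by the same peak. Their count is thus not one of independent members, as the random lists treat it. Of 22 lysine acyl writer, eraser and reader genes 17 and 19 were marked, of 30 cell cycle genes 20 and 24, and of 30 genes of mitochondrial respiration and the TCA cycle 20 and 25. Developmental transcription factor genes were marked in 1 and 4 of 33. The 5 lists of other cell types, neuronal, blood, fibroblast, endothelial and liver, had 16 of 91 members marked in each library (17.6%). By list, in the library labelled untreated and then the library labelled lactate, these were 4 and 4 of 20 neuronal, 5 and 4 of 20 blood cell, 3 and 4 of 16 fibroblast, 3 and 1 of 15 endothelial and 1 and 3 of 20 liver markers. Of 21 angiogenesis genes 6 were marked in each library, 5 of them in both, with VEGFA in the library labelled lactate alone and VEGFB in the library labelled untreated alone.

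Between the libraries, the list of growth factor, AP-1 and YAP signalling genes had 18 of 32 members marked in the library labelled untreated and 25 in the library labelled lactate, with 7 in the latter alone and 0 in the former alone, a difference at the 99.1th percentile of random lists, the highest of the 19 lists with all peaks. The 7 included the EGF family ligand genes EREG and AREG, with fold enrichments of 5.51 and 5.16. Also among them were TEAD1, the YAP partner gene, with 4.46, and BMP4 with 4.35. The random lists treat members as independent, and EREG and AREG, in 1 stretch of chromosome 4, may not be so. With equal lists of the strongest regions the difference was 1 gene, below those of the mitochondrial respiration (4), lysine acyl (3) and neuronal (2) lists, and at a fold enrichment of at least 5 it was 7 genes, below the 8 of ribosomal proteins. With all peaks, the next highest percentile was 94.2, of the mitochondrial respiration list. The lowest was 2.08, of the endothelial list, with 1 gene in the library labelled lactate alone and 3 in the other alone. These ranks would turn if the peak lists were exchanged. The highest and lowest of 19 percentiles are extreme by selection alone, and no allowance was made for this. Of 22 hypoxia genes, 14 and 17 were marked, with P4HA2 (5.71), EPAS1 (3.88) and VEGFA in the library labelled lactate alone. The squamous epithelium list had 16 and 21 of 38, with KRT6A (4.72), KRT10 (4.56) and IVL (3.53) in the library labelled lactate alone and SPRR3 (3.40) in the library labelled untreated alone. The interferon, antigen presentation and inflammation list had 18 and 22 of 32, with NFKB1 (6.96), HLA-C (5.41), RELA (4.15) and HLA-B (4.05) in the library labelled lactate alone and OAS1 (4.92) in the library labelled untreated alone. HLA-B and HLA-C share sequence with each other, so their reads are uncertain. UQCRFS1, NDUFS1 (4.95), COX6C (4.92) and NDUFA9 (4.56), all of the respiratory chain, were marked in the library labelled lactate alone, as were RB1, MCM2, CDKN1B and CCND1 of the cell cycle list and HDAC3 and TRIM33 of the lysine acyl list. The differences of the hypoxia, squamous, interferon and cell cycle lists, at percentiles of 83.4 to 88.0, shrank with equal lists from 3 to 1, 5 to 1, 4 to 0 and 4 to 0 genes.

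Glycolysis and lactate transport genes were marked in 19 of 26 in the library labelled untreated and 18 in the library labelled lactate, ALDOC being the gene in the library labelled untreated alone. Of 39 genes of epithelial-mesenchymal transition and invasion, 17 and 19 were marked, with ITGB1, FN1, TGFBI and MMP1 among 7 in the library labelled lactate alone, and MMP10, VIM and LOXL2 among 5 in the library labelled untreated alone. These 5 include PLAUR, whose peak overlapped one of the other library, and without such peaks the difference of this list was 3 genes in place of 2. The direction of the difference in the glycolysis, epithelial-mesenchymal, ribosomal and DNA repair lists turned under stricter peak thresholds and with equal lists, and that of the histone list, 3 genes, turned to -3 with equal lists. In all, 13 lists had more members in the library labelled lactate alone, 4 had fewer and 2 had as many, against the 2.59-fold excess over all genes.

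**Figure D2:**
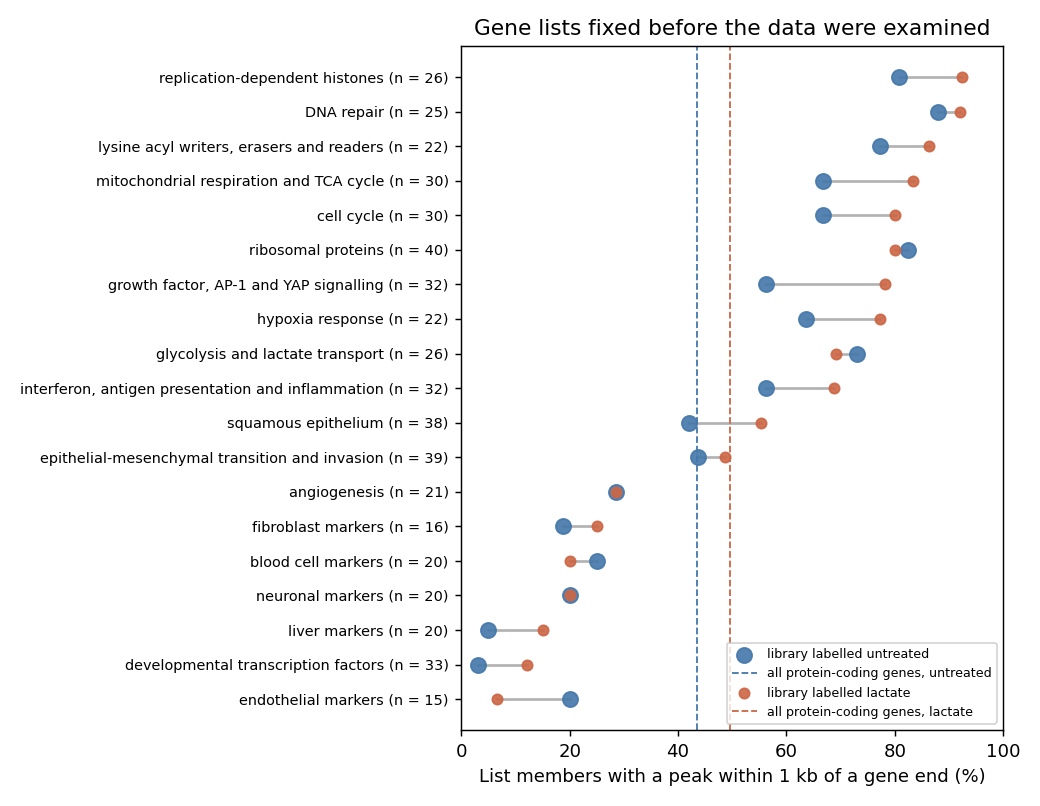
Percent of each gene list's members with a peak within 1 kb of a gene end (horizontal axis) for 19 lists (vertical axis, n is the number of members found); large blue points are the library labelled untreated, small orange points the library labelled lactate, and dashed lines the share of all protein-coding genes, 43.5% and 49.5%. Each point is 1 library; the growth factor, AP-1 and YAP list went from 18 to 25 of 32 members, and ribosomal proteins stood at 33 and 32 of 40.

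**Figure D3:**
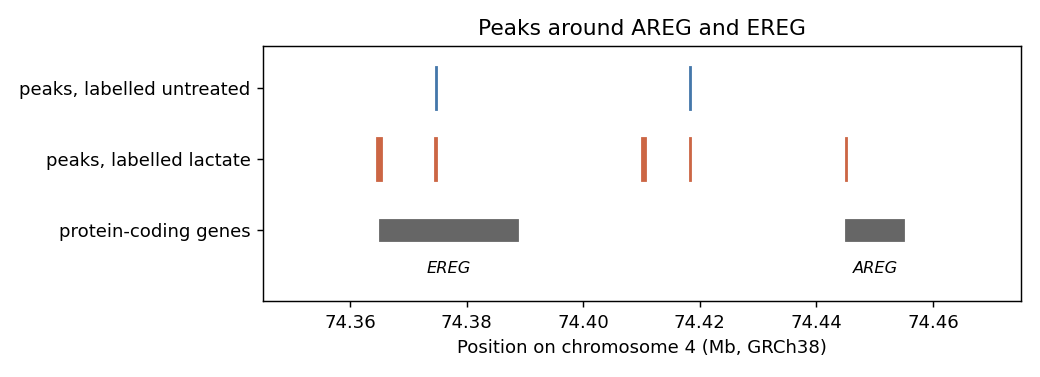
Peak regions (coloured boxes) of both libraries around EREG and AREG (grey boxes) on chromosome 4 from 74345145 to 74475005, position in Mb on GRCh38; the stretch was chosen after its values were seen. The library labelled lactate had 5 regions, among them those at the ends of EREG and AREG, and the library labelled untreated had 2.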

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

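The tests in this part were chosen after the results were seen, except the equal-list ratio, an alternative planned before, and the limits that the values were held against were set afterwards for each of them.

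Signal appeared on mitochondrial and unplaced sequences, which the location and gene comparisons left out. The median local background of the mitochondrial peaks was 162.1 per 1000000 tags in the library labelled untreated and 293.6 in the library labelled lactate. Unplaced sequences held 220 peaks in the library labelled untreated and 197 in the library labelled lactate.

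The header conflict touches every direction in the report. All 108679 summits carry the name of the other sample. An exchange of the lists between the samples would give this, and so would an error in naming that reached the input file. An error in the run name alone is argued against, since the input file also carries the other sample's name in both lists. The name line of each header, however, carries the label's name and differs from the run name in the same list. An exchange alone would have moved that line too, so neither explanation was shown to account for the whole header. The 2 cannot be told apart, because no value in the lists ties a library to its treatment.

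The library labelled lactate had more peaks. Sequencing depth is argued against as the cause, since it had 0.963 times as many tags. Background spread evenly over the genome is argued against as the source of all regions in the library labelled lactate alone. These lay at gene ends 6.30 times as often as bases of the genome do, against 9.75 times for its shared regions. A part of them could still be such background, and the value says nothing of background tagmentation in open chromatin. For the regions in the library labelled untreated alone the value was 4.05 times. A library-wide difference in enrichment cannot be told apart from a difference at particular genes: equal lists gave a ratio of 1.26, but equal lengths push this ratio toward 1 with or without that cause. At shared regions the median fold enrichment was 5.47 in the library labelled lactate and 4.97 in the library labelled untreated, and the median pileup 18 and 16. At genes marked in both, the median fold enrichment was 5.88 and 5.27. These values go with a library-wide difference but do not settle its cause. An effect of lactate stays open and untested, with 1 library per group.

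Sites called in 1 library alone may largely be weak sites near the calling threshold, as a hypothesis: 68.6% of the weakest and 5.98% of the strongest 25% in the library labelled lactate were in that library alone, a ratio of 11.5, and 57.5% and 3.20% in the library labelled untreated, a ratio of 18.0. Peak edges at the limit of the gene-end window are argued against as the whole cause, since 2.37% of the genes marked in the library labelled lactate alone (46 genes) had such a peak.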

How the results depend on the processing

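The alternatives were set before the data were examined, except those on gene-end peaks that overlap no peak of the other library, on length-matched lists and on library-alone peaks of like strength, which were chosen after seeing the data. In the counts of genes over each alternative run, the library labelled lactate alone had more than the library labelled untreated alone, by ratios from 1.26 to 5.82. Only the equal lists, which gave 1.26, had the same number of regions from each library. The library labelled untreated kept 17310 regions under the fold alternative and 21627 under the −log10 p alternative, and the library labelled lactate 23840 and 28598. With fold enrichment of at least 5, the peak ratio was 1.38, shared shares 72.8% (library labelled untreated) and 52.7% (library labelled lactate), gene-end shares 22.9% and 21.7%, and the gene ratio 2.94. With recomputed −log10 p of at least 7 they were 1.32, 77.3% and 58.1%, 23.8% and 23.1%, and 3.07. Under both, the order of the libraries in the gene-end share turned. With equal lists, sharing was 68.2% and 67.5%, gene-end shares 23.8% and 24.6%, genes in the library labelled untreated alone 1150, and the ratio 1.26. Sharing was 55.6% and 48.2% with reciprocal overlap of 50%, 65.0% and 52.4% with 50% of the peak, 76.4% and 68.2% with gaps up to 1 kb, and 96.8% and 94.0% for the strongest 25% of peaks. With gene ends within 3 kb the gene ratio was 2.37 and gene-end shares 25.6% and 26.6%, and by covered bases 22.5% and 23.5%. The strongest 25% with no other peak within 5 kb gave 64 and 11 genes, a ratio of 5.82. No list member was among these genes. Every list difference was thus 0 there, which says nothing of the lists. Of 152 list differences 56 stayed as they were, 80 moved and 16 turned, given here as members in the library labelled lactate alone minus the other. Under the fold, −log10 p and equal-list alternatives in turn, glycolysis went from -1 to 5, 4 and 1, epithelial-mesenchymal transition from 2 to -1, -2 and -2, ribosomal proteins from -1 to 8, 4 and 1, and DNA repair from 1 to -3, -2 and -3. Histones went from 3 to -3 with equal lists, blood markers from -1 to 1 under the fold alternative and within 3 kb, and endothelial markers from -2 to 1 within 3 kb. The cause was not tested. With the added rule the gene ratio was 2.65, and for library-alone peaks of like strength the gene-end share was 1.58 times as high in the library labelled lactate, against 1.56. With length-matched random lists the difference of the growth factor, AP-1 and YAP list lay at the 98.9th percentile, against the 99.1th. Alternatives by q, transcription start, 5′ end, promoter GC and motifs were not run. No paired analysis was possible because each group has 1 library. At this depth weak peaks were shared least.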

Other observations

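The families and regions here were chosen after their values were seen, from 34 symbol families and 7 gene types looked at. Olfactory receptor genes, silent in most tissues, were marked in 11 of 392 in the library labelled untreated (2.81%) and 6 in the library labelled lactate (1.53%). None of 25 bitter taste receptor genes and none of 39 beta defensin genes was marked in either. Genes of mitochondrial ribosomal proteins were marked in 54 of 77 (70.1%) and 61 of 77 (79.2%), with 7 in the library labelled lactate alone and 0 in the library labelled untreated alone. Among 30 integrin genes 9 and 14 were marked, among 44 collagen genes 10 and 16, and among 55 keratin genes 8 and 14. Of 429 tRNA genes, 211 (49.2%) and 252 (58.7%) had a peak at an end, and many are near-identical copies. Genes on chromosome X were marked least of those on chromosomes 1 to 22 and X, at 22.9% and 28.1%, and those on chromosome 2 most, at 51.4% and 58.0%.

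The densest 100-kb window of the library labelled lactate lay on chromosome 11 from 65400001 to 65500000, over the nuclear long noncoding RNA genes NEAT1 and MALAT1, with 18 regions against 11 in the library labelled untreated. The next window, from 65500001 to 65600000, which also holds part of MALAT1, had 10 against 12. The densest window of the library labelled untreated lay on chromosome 4 from 49100001 to 49200000, with 15 regions against 13 in the library labelled lactate, and the window of STK11 and CIRBP on chromosome 19, from 1200001 to 1300000, had 14 against 12. The chromosome 4 window held no protein-coding gene, and its reads are uncertain, since repeat and artefact-prone stretches were not filtered out. Elsewhere on chromosome 11, in the library labelled lactate and then the library labelled untreated, the windows over ABTB2 held 11 and 12 (from 34200001 to 34300000) and 14 and 11 (from 34300001 to 34400000), that of CAT and ELF5 9 and 12 (from 34400001 to 34500000), and that of EHF, an epithelial ETS factor gene, 12 and 11 (from 34600001 to 34700000). The window of the lactate transporter gene SLC16A3, on chromosome 17 from 82200001 to 82300000, held 13 and 11 in the same order, that of DUSP1 on chromosome 5 held 13 and 10, and those of PADI1 with PADI3 and of S100A2 to S100A6, epidermal gene clusters on chromosome 1, both held 12 and 8. Of the regions in the library labelled lactate alone, 19.8% (interval 19.2 to 20.3) lay within 5 kb of a shared region, against 14.2% in the library labelled untreated (interval 13.6 to 14.8) and 9.79% and 9.76% at random positions.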
